A study of Mus musculus with 9 samples.

How the data were processed

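Colonic tissue of mice was profiled by stranded sequencing of poly(A) RNA with adapters that carried molecular identifiers, per the labels' protocols. The 9 libraries formed 3 groups of 3: chow with AOM/DSS, high-fat diet with AOM/DSS, and berberine. The labels give AOM/DSS only as an abbreviation, which usually stands for azoxymethane and dextran sulfate sodium, a chemical model of colitis-associated colon tumours. The labels do not say which diet the berberine group received, whether it received AOM/DSS, or whether the 9 libraries came from 9 animals.

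The deposited table holds, per the file headers, an estimated count and an FPKM value for each gene in each library. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.0.4, UMI-tools, StringTie 1.3.4d, DESeq2 and edgeR were used with the mouse build GRCm38, but the notes do not state which step each tool served or which filters were set. The deposited estimated counts are whole numbers that are not normalised between libraries. Low counts piled up at multiples of 4, and the ratio of count to FPKM was fixed up to 1 factor per library, so 1 sequenced fragment appears to be worth about 4 of these counts. The deposited FPKM values are listed at 0.0001 wherever the count is 0. The totals ran from 51961764 to 69007117 estimated counts per library, and at this depth 1 fragment of a gene is about 4 counts. Of 55401 entries in the table, 20961 had a count of 0 in every library.

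The main test was edgeR 4.0.16 (quasi-likelihood fits with TMM scaling) on the estimated counts of all 9 libraries, with limma 3.58.1 for gene sets, in R 4.3.3. The design written before the data were examined had assumed FPKM values and limma on log2(FPKM + 1). It was replaced by edgeR because the table also held counts, and the limma fit was kept as an alternative. A total of 14506 genes with a mean of at least 1 FPKM over the 9 libraries were tested, and these held 98.9% of all counts. A gene is said to have changed, risen or fallen when its Benjamini-Hochberg adjusted p was under 0.05 over all tested genes. All 3 pairs of groups were compared. Values per gene are CPM, the counts scaled to a common library size, on the TMM-scaled library sizes, given as mean ± SD with n = 3 per group, and log2 fold changes are given ± SE.

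A total of 37 gene lists with 551 genes were fixed before the files were seen, of which 486 genes were tested. They cover Wnt targets and crypt stem cells, cell division, regenerative epithelium, inflammatory mediators, interferon response, MHC class II, antimicrobial proteins, tight and adherens junctions, fatty acid oxidation and PPAR targets, fatty acid synthesis, cholesterol synthesis, phospholipid and lysophosphatidylcholine metabolism, bile acid handling, xenobiotic response, oxidative stress response, unfolded protein and amino acid stress response, oxidative phosphorylation, glycolysis and hypoxia, and immediate early genes. They also hold markers of absorptive colonocytes, goblet cells, enteroendocrine cells, tuft cells, neutrophils, macrophages, T and NK cells, follicular B cells, plasma cells, mast cells, smooth muscle, fibroblasts and matrix, endothelium, adipocytes, enteric neurons and glia, squamous epithelium and pancreatic acinar cells, with posterior Hox genes as a guide to position. Another 4 lists were added after values had been seen: striated muscle, proximal colon, heat shock proteins and general epithelium. The heat shock list was written after 3 of its members had been seen among the called genes. The general epithelium list was written after 8 of its 18 members had been seen, and 7 other epithelial genes that had been seen were left out of it.

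Lists were tested with camera at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison, with an estimated correlation and with fry as alternatives. Counts of members are given over all genes tested and adjusted over the list alone. Members low in every group were not tested, while a gene near 0 in 1 group could pass the filter through another group. Of the inflammatory mediators 13 of 20 were tested, and of the neutrophil genes 5 of 12. Counts and medians of a list therefore describe its tested members and not the whole list. Terms that the table pairs with genes were tested the same way where they held 10 to 300 tested genes. A list score is the mean over members of log2(CPM + 1), less the chow mean.

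Genes are named by a rule. Per comparison it takes the 10 highest and the 10 lowest fold changes among genes that changed, whose groups did not overlap and whose symbol is unique, leaving out predicted models and immunoglobulin or T cell receptor segments. Where none passed in a direction, the 5 with the smallest p stand in. It adds the 4 members of each fixed list with the smallest p, and members needed as markers. Against a group at 0 in every library, a fold is a lower bound computed from a floor of 12 counts, or 3 fragments, over the group. Intervals and floors cover counting error only, at a level of 95%.

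The analysis was tested on simulated counts drawn from the mean of each gene over all 9 libraries, with 1 dispersion per gene. In each run 100 genes were changed 2-fold and 100 changed 4-fold among 14506. In high-fat diet against chow, 25% of the 2-fold and 79% of the 4-fold genes were recovered with 1 false call. For berberine against high-fat diet the shares were 22% and 70% with 4 false calls, and for berberine against chow they were 14% and 68% with 4 false calls. The runs used the same means and dispersions and differed mainly in the random draw. Differences between their shares therefore do not rank the comparisons. The adjusted p depends on how many genes change. These shares therefore do not carry over to the real comparisons, where 4613, 4460 and 7 genes were called. For sequence copies, transcripts of GENCODE vM21 were compared with BLAST 2.17.0, and a match of at least 300 bases at 95% identity counted as near-identical.

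Alternatives covered pseudocounts, filters on low values, scalings, variance models, calling rules, the replicate number as a block, the groups in the fit, and each library left out in turn. Limma on log2(FPKM + 1), the main test of the written design, became an alternative when edgeR replaced it. Chosen after seeing the data were DESeq2 1.42.0, library totals without TMM, counts divided by 4, and 3 pairs of libraries left out. No library was left out of the main test.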

Results

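RNA from colonic tissue was sequenced in 9 mouse libraries, 3 from a chow group and 3 from a high-fat diet group, both with AOM/DSS, and 3 from a berberine group. Berberine is a plant alkaloid, and the series asks about its action against tumours at the level of gene expression. The diet of the berberine group is not in the labels. Library totals ran from 51961764 estimated counts in berberine replicate 1 to 69007117 in berberine replicate 2. On the first principal component, which held 56.1% of the variance, the high-fat diet libraries lay between 94.75 and 100.63 and all other libraries between -52.03 and -42.3. Some libraries stood apart for genes of other tissues. The striated muscle score was 3.72 in chow replicate 3 and at most -1.68 elsewhere. The proximal colon score was 2.60 in chow replicate 2 and at most -0.96 elsewhere. The squamous epithelium score was 2.12 in chow replicate 1 and -1.18 and -0.95 in the other chow libraries. It ran from 0.74 to 1.51 in the high-fat diet libraries and from -1.26 to -0.63 in the berberine libraries. The adipocyte score was 2.76 and 2.46 in berberine replicates 1 and 2, -1.67 in berberine replicate 3 and at most 0.69 elsewhere.

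High-fat diet was first compared with chow, which asks how the diet altered the colon under AOM/DSS. In the high-fat diet libraries, most Wnt target genes, inflammatory mediators and mast cell genes and some regenerative epithelial genes were higher, while most genes of absorptive, goblet and enteroendocrine cells, of xenobiotic metabolism and of T and B cells were lower. Of these lists, those of Wnt targets and enteroendocrine cells kept their call with an estimated correlation, and the others lost it. Prox1, a transcription factor gene of the Wnt programme (ENSMUSG00000010175, GRCm38 chromosome 1, 190118035 to 190170714), rose from 7.82 ± 0.87 to 378 ± 25.7 CPM, or 48.3-fold. Aqp8, a water channel of surface colonocytes (ENSMUSG00000030762, chromosome 7, 123462291 to 123468004), fell from 689 ± 104 to 13.5 ± 6.72 CPM, or 50.8-fold. By edgeR, 4613 of 14506 genes changed, 2199 upward and 2414 downward, and 2462 of them by at least 2-fold.

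Wnt targets and crypt stem cell genes rose in 19 of 21 tested members and fell in 1 (20 and 1 adjusted over the list alone), with a median log2 fold change of 2.66. Notum, a secreted Wnt inhibitor, went from 0.48 ± 0.37 to 296 ± 82.0 CPM, and Nkd1, another Wnt feedback gene, from 42.4 ± 7.49 to 700.5 ± 288 CPM. Smoc2, a crypt base gene, went from 21.6 ± 2.88 to 200 ± 53.9 CPM. The list held with an estimated correlation (camera adjusted p = 9.74e-27 preset and adjusted p = 0.0158 estimated). Cell division genes rose in 6 of 25 members (4 adjusted over the list alone), among them Mcm7 (log2 fold change 1.16 ± 0.21) and Mcm2 (1.11 ± 0.26), both of the replicative helicase, and the list's call was lost (adjusted p = 0.676 with an estimated correlation). Regenerative epithelium genes rose in 8 of 15 members (10 adjusted over the list alone). Krt7, a keratin, rose by 2.23 ± 0.12 and Mmp7, a matrix protease, by 5.79 ± 1.08 on the log2 scale, and the list had adjusted p = 0.176 with an estimated correlation.

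Inflammatory mediators rose in 11 of the 13 members tested out of 20 (13 adjusted over the list alone). Those tested had a median log2 fold change of 3.78. Il23a, a cytokine subunit, rose from 0.396 ± 0.134 to 27.7 ± 6.92 CPM, and the neutrophil chemokines Cxcl1 and Cxcl2 by 4.45 ± 0.54 and 7.10 ± 0.78 on the log2 scale. The list had adjusted p = 0.367 with an estimated correlation. Antimicrobial proteins rose in 5 of 12 members and fell in 1, counts that were equal adjusted over the list alone. Pla2g2a, a secreted phospholipase, went from 51.9 ± 37.2 to 8464 ± 4171 CPM, and Pigr, the transporter of IgA, fell from 2741 ± 979 to 879 ± 297 CPM. The list had adjusted p = 0.595 with an estimated correlation, and its preset call (adjusted p = 0.0269) was lost without high-fat diet replicate 2 (adjusted p = 0.0737) or chow replicate 3 (adjusted p = 0.156). Mast cell genes rose in 8 of 9 members and fell in 1, also adjusted over the list alone. Mcpt1 and Mcpt2, mast cell proteases, averaged 1046 ± 1224 and 586 ± 674 CPM against 1.19 ± 0.11 and 0.61 ± 0.28 in chow, and the list scores of the high-fat diet libraries ran from 3.14 to 6.62. Their log2 fold changes of 9.77 and 9.89 became 8.19 for Mcpt1, high-fat diet against chow, and 8.35 for Mcpt2, high-fat diet against chow, without high-fat diet replicate 1. The list's median was 9.51, or 8.50 with Tpsab1 and other genes absent from chow at their bound, with adjusted p = 0.54 with an estimated correlation.

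Absorptive colonocyte genes fell in 12 of 16 members (14 adjusted over the list alone), with a median of -2.63. Slc26a3, the chloride and bicarbonate exchanger, went from 767 ± 166 to 24.8 ± 15.4 CPM, Mep1a, a brush border protease, fell by 3.28 ± 0.34 and Slc5a8, a transporter of short-chain fatty acids, fell by 3.17 ± 0.39 on the log2 scale. Goblet cell genes fell in 9 of 13 members (11 adjusted over the list alone), among them Atoh1, the secretory lineage factor (-2.49 ± 0.28), and Agr2 (-2.50 ± 0.42). Enteroendocrine genes fell in 7 of 10 members (7 adjusted over the list alone), with Gcg, the precursor of glucagon-like peptides, at 2.87 ± 0.66 against 49.5 ± 11.3 CPM and Insl5 at 7.54 ± 4.25 against 83.2 ± 33.5 CPM. The enteroendocrine list held with an estimated correlation (adjusted p = 0.0487), whereas absorptive and goblet lists had adjusted p = 0.176 and adjusted p = 0.515 with an estimated correlation. Of the lists added after values were seen, proximal colon genes fell in 4 of 6 members (5 adjusted over the list alone), with the high values in chow replicate 2 (adjusted p = 0.567 with an estimated correlation). General epithelial genes rose in 2 of 18 members and fell in 0 by edgeR, with a median of -0.08 that the camera test did not call (adjusted p = 0.921).

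Xenobiotic response genes fell in 12 of 14 members (12 lower and 1 higher adjusted over the list alone), with a median of -3.17. Abcb1a, the drug efflux pump, went from 663 ± 375 to 25.3 ± 9.74 CPM and Cyp3a13, a cytochrome P450, from 46.7 ± 18.2 to 3.84 ± 1.25 CPM. Bile acid handling genes fell in 9 of 11 members and rose in 1 (9 and 2 adjusted over the list alone). Vdr, the vitamin D receptor, went from 373 ± 53.8 to 57.9 ± 17.9 CPM and Nr1i2, the pregnane X receptor, fell by 1.51 ± 0.15 on the log2 scale, while Abcc2, a conjugate exporter, rose from 0.864 ± 0.301 to 30.2 ± 22.1 CPM. Fatty acid oxidation and PPAR targets fell in 11 of 20 members (12 adjusted over the list alone), with the mitochondrial enzymes Acaa2 at -1.81 ± 0.18 and Hadhb at -1.44 ± 0.17. Nuclear genes of oxidative phosphorylation fell in 13 of 25 members (15 lower and 1 higher adjusted over the list alone), including Sdhb (-0.92 ± 0.16). These 4 lists had adjusted p = 0.13, 0.289, 0.572 and 0.572 with an estimated correlation. In phospholipid and lysophosphatidylcholine metabolism 5 of 20 members rose and 5 fell (6 and 7 adjusted over the list alone), without a list call (adjusted p = 0.958). Lpcat4, which reacylates lysophospholipids, rose from 30.4 ± 7.19 to 158 ± 6.98 CPM and the phospholipase gene Pla2g12a rose by 1.81 ± 0.18, whereas Enpp2, which makes lysophosphatidic acid, and Mboat1 fell by 2.43 ± 0.31 and 1.61 ± 0.20 on the log2 scale.

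MHC class II genes fell in all 9 tested members (9 adjusted over the list alone), with Cd74, the invariant chain, at -1.25 ± 0.28 and Ciita, the class II activator, at -1.47 ± 0.35. T and NK cell genes fell in 7 of 13 members and rose in 1 (9 and 1 adjusted over the list alone), with Cd4 at -1.52 ± 0.25 and Cd3e at -2.25 ± 0.42. Follicular B cell genes fell in 11 of 14 members (12 adjusted over the list alone), with Cd22 at -1.40 ± 0.33 and Fcmr at -1.69 ± 0.39. Of 181 immunoglobulin and T cell receptor segments tested, 1 rose and 17 fell. These lists had adjusted p = 0.572 each with an estimated correlation. Smooth muscle genes fell in 6 of 12 members (12 adjusted over the list alone), with Mylk at -1.96 ± 0.42, although high-fat diet replicate 3 scored -0.64 against -2.84 and -2.27 in the others, and the list had adjusted p = 0.572 with an estimated correlation. Enteric neurons and glia fell in 3 of 8 members (3 adjusted over the list alone, adjusted p = 0.572 with an estimated correlation). Adipocyte genes fell in 1 of 11 members (0 adjusted over the list alone, adjusted p = 0.734 with an estimated correlation), and the preset call (adjusted p = 0.0491) was lost without high-fat diet replicate 2 (0.0821) or 3 (0.093) or chow replicate 2 (0.146).

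No call was made at the preset correlation for the remaining lists. Members higher and lower over all genes were 1 and 4 of 20 for interferon response, 1 and 4 of 16 for tight and adherens junctions, 3 and 1 of 14 for fatty acid synthesis, 0 and 1 of 20 for cholesterol synthesis, and 2 and 2 of 11 for oxidative stress response. They were 4 and 0 of 14 for unfolded protein and amino acid stress response, 1 and 3 of 19 for glycolysis and hypoxia, and 2 and 1 of 12 for immediate early genes. They were 1 and 0 of 5 for tuft cells, 4 and 0 of 5 for neutrophils, 3 and 0 of 11 for macrophages, 0 and 2 of 9 for plasma cells, 2 and 3 of 15 for fibroblasts and matrix, 0 and 3 of 9 for endothelium, 2 and 0 of 9 for squamous epithelium, 0 and 0 of 1 for pancreatic acinar cells, and 0 and 1 of 8 for posterior Hox genes. Adjusted over the list alone, the counts differed for tight and adherens junctions (2 and 5), cholesterol synthesis (0 and 0), immediate early genes (2 and 0), tuft cells (1 and 1), macrophages (5 and 0) and plasma cells (0 and 0). Within these, Cldn4, a tight junction protein, rose by 2.25 ± 0.26, Jun and Ier3, early response genes, rose by 1.17 ± 0.15 and 2.59 ± 0.23, Avil of tuft cells rose by 3.75 ± 0.44, and Cd14 rose by 1.48 ± 0.18 on the log2 scale. The fibroblast gene Lum fell by 2.44 ± 0.33, the Hox gene Hoxa13 fell by 1.26 ± 0.19, and Fasn, the fatty acid synthase, rose by 1.02 ± 0.23. Several lists gained a call without a single library: neutrophils, macrophages and unfolded protein response without high-fat diet replicate 3 (adjusted p = 0.00115, 0.0268 and 0.0268), macrophages without chow replicate 3 (0.0133), interferon response, downward, without high-fat diet replicate 2 (0.00387), and plasma cells and squamous epithelium without chow replicate 1 (0.0292 and 0.0027). Median, mean and camera direction differed in sign for fatty acid synthesis, phospholipid metabolism, glycolysis and hypoxia, tuft cells, fibroblasts and matrix, squamous epithelium, posterior Hox genes and general epithelium.

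Several genes that rose were absent from every chow library, so their folds are lower bounds. The mast cell genes Tpsab1 and Cma2 were at least 2180-fold and 619-fold higher, the transcription factor gene T at least 541-fold higher, Prss56 at least 524-fold higher and Cyp21a1 at least 367-fold higher. The bounds of Tpsab1, Cma2, T and Prss56 rest mostly on high-fat diet replicate 1. There Tpsab1, Cma2 and Prss56 were at 374, 105 and 68.6 CPM, against at most 48.8, 13.8 and 18.7 CPM in the other libraries. The defensin genes Defa24, Defa17, Defa30, Defa3 and Defa35 were at least 983-fold, 726-fold, 630-fold, 539-fold and 386-fold higher. Defensin genes have closely related sequences, and how reads were shared among them was not tested. Large falls included Cyp2c55, a cytochrome P450, from 1527 ± 1655 to 3.86 ± 1.70 CPM, Ces1e, a carboxylesterase (-7.23 ± 0.95), and Slc30a10, a manganese exporter (-7.07 ± 0.98). Cyp2c55 was at 3419 CPM in chow replicate 2 and at 820 and 344 CPM in chow replicates 1 and 3. For Cyp2c55, high-fat diet against chow, the log2 fold change was -8.62 with all libraries and -7.22 without chow replicate 2. Striated muscle genes fell in 9 of 10 members (10 adjusted over the list alone, adjusted p = 0.605 with an estimated correlation), with the high values in chow replicate 3. Without that library adjusted p was 0.18 for Tnnc2, 0.192 for Myoz1 and 0.198 for Actn3. Myh4, a myosin gene at 0 under high-fat diet, was at 669.9 CPM in chow replicate 3 and at 0.343 and 0.321 CPM in chow replicates 1 and 2. For Myh4, high-fat diet against chow, adjusted p was 0.00526 without chow replicate 3, and the value of 0.0437 with all libraries became 0.0703, 0.0702 and 0.0696 without berberine replicates 1, 2 and 3 and 0.0914, 0.0916 and 0.0838 without high-fat diet replicates 1, 2 and 3. Without chow replicates 1 and 3 together 2756 genes changed, and without chow replicates 2 and 3 together 2001 changed, in fits where the lone chow library is assumed to vary like the other groups. With scaling by library totals alone the median of all genes was 0.128, against 0.002 with TMM, and edgeR gave 2807 genes higher and 1890 lower, 59.8% higher in place of 47.7%. In 45.7% of genes the groups did not overlap, where chance gives 10%.

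**Figure D1:**
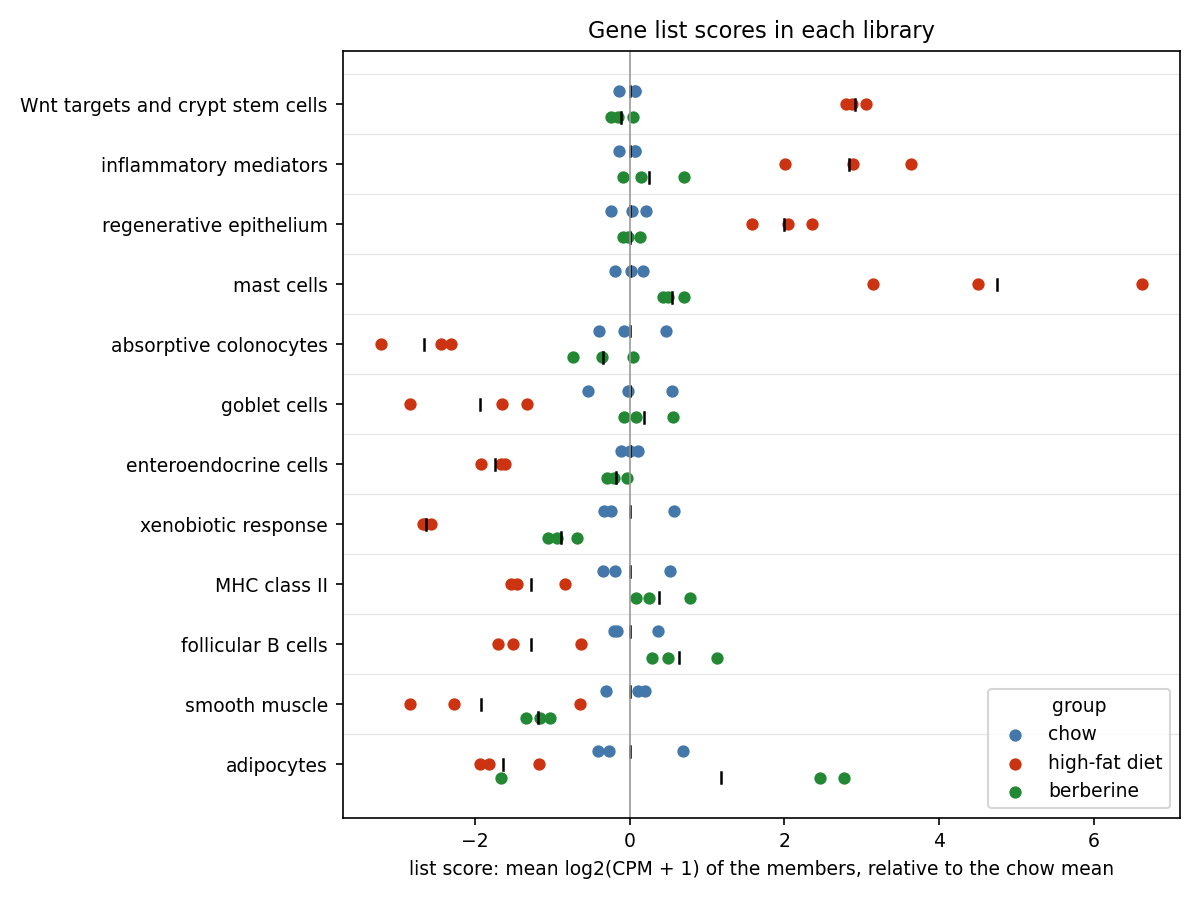
Each point is the score of a gene list (mean log2(CPM + 1) of its members, less the chow mean) in 1 library, with a bar at the group mean of 3 libraries. For Wnt targets and crypt stem cells the high-fat diet libraries lay between 2.80 and 3.06 and no other library was above 0.07.

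Berberine was then compared with high-fat diet, which asks how the berberine libraries differed from the diet group. Many Wnt target, inflammatory and mast cell genes were lower in the berberine libraries, and many colonocyte, goblet, enteroendocrine, xenobiotic and lymphocyte genes were higher. Of these lists, that of Wnt targets kept its call with an estimated correlation, and the others lost it. Prox1 was 7.52 ± 1.53 against 378 ± 25.7 CPM, or 50.2-fold lower, and Nkd1 was 19.4 ± 4.27 against 700.5 ± 288 CPM. Selenbp1, a selenium-binding protein of differentiated colonocytes (ENSMUSG00000068874, chromosome 3, 94933056 to 94944758), was 1285 ± 371 against 36.2 ± 5.42 CPM, or 35.5-fold higher, and Aqp8 was 31.0-fold higher. By edgeR, 4460 of 14506 genes changed, 2292 upward and 2168 downward, and 2371 of them by at least 2-fold.

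Wnt targets and crypt stem cell genes fell in 19 of 21 members (19 lower and 1 higher adjusted over the list alone), with a median of -2.72, and this was the list that held with an estimated correlation (adjusted p = 0.00777). Regenerative epithelium fell in 9 of 15 members (10 adjusted over the list alone), with Krt7 at -2.36 ± 0.12 and Mmp7 at -7.59 ± 1.18. Inflammatory mediators fell in 9 of the 13 members tested out of 20 (9 adjusted over the list alone), with Il23a at -5.15 ± 0.53 and Cxcl2 at -5.65 ± 0.72. Mast cell genes fell in 7 of 9 members and rose in 1 (8 and 1 adjusted over the list alone), with Mcpt1 at -7.70 ± 1.07. Their list scores were uneven under high-fat diet, at 6.62, 4.49 and 3.14 in replicates 1, 2 and 3. Cell division genes fell in 3 of 25 members (3 adjusted over the list alone), with Cdk1 at -1.13 ± 0.22. Antimicrobial proteins fell in 5 of 12 members and rose in 1, also adjusted over the list alone, with Pla2g2a at -7.83 ± 1.08 and Pigr at 2.14 ± 0.35. That call (adjusted p = 0.0296) was lost without berberine replicate 1 (0.06) or high-fat diet replicate 2 (0.0771). Squamous epithelium fell in 2 of 9 members (2 adjusted over the list alone), with Krt15 at -4.79 ± 0.87. With an estimated correlation the calls were lost, with adjusted p = 0.226 for regenerative epithelium, 0.411 for inflammatory mediators, 0.523 for mast cells, 0.645 for cell division, 0.645 for antimicrobial proteins and 0.571 for squamous epithelium.

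Absorptive colonocyte genes rose in 11 of 16 members (12 adjusted over the list alone), with Slc26a3 at 561 ± 124 against 24.8 ± 15.4 CPM. Goblet cell genes rose in 9 of 13 members (9 adjusted over the list alone), with Tff3, a mucus peptide, at 1396 ± 257 against 246 ± 114 CPM. Enteroendocrine genes rose in 5 of 10 members (6 higher and 1 lower adjusted over the list alone), with Gcg at 3.68 ± 0.27. Xenobiotic response genes rose in 9 of 14 members and fell in 1 (11 and 1 adjusted over the list alone), with Ces2c, a carboxylesterase, at 3.64 ± 0.52 and Abcb1a at 3.27 ± 0.45. Bile acid handling genes rose in 6 of 11 members and fell in 1 (7 and 2 adjusted over the list alone), with Vdr at 2.42 ± 0.23 and Abcc2 at -5.55 ± 0.71. Fatty acid oxidation and PPAR targets rose in 8 of 20 members and fell in 2, also adjusted over the list alone, with Hadhb at 1.11 ± 0.17. Oxidative phosphorylation genes rose in 14 of 25 members (17 higher and 1 lower adjusted over the list alone), with Sdha at 0.94 ± 0.18. The adjusted p with an estimated correlation was 0.237 for absorptive colonocytes, 0.411 for goblet cells, 0.0654 for enteroendocrine cells, 0.226 for xenobiotic response, 0.411 for bile acid handling, 0.658 for fatty acid oxidation and 0.628 for oxidative phosphorylation. Members of phospholipid and lysophosphatidylcholine metabolism moved both ways, 5 of 20 up and 6 down (6 and 6 adjusted over the list alone), with Lpcat4 at -2.71 ± 0.18, Pla2g12a at -2.53 ± 0.19 and Enpp2 at 2.78 ± 0.32.

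Many lymphocyte genes were higher in the berberine libraries. All 14 follicular B cell genes rose (14 adjusted over the list alone), with Fcmr at 71.9 ± 24.9 against 13.1 ± 6.66 CPM. All 9 MHC class II genes rose (9 adjusted over the list alone), with Cd74 at 1.67 ± 0.28. T and NK cell genes rose in 9 of 13 members and fell in 1 (10 and 2 adjusted over the list alone), with Cd4 at 1.94 ± 0.25. Plasma cell genes rose in 6 of 9 members (6 adjusted over the list alone), with Derl3 at 2.57 ± 0.40, and 54 of 181 immunoglobulin and T cell receptor segments rose and 0 fell by edgeR. These 4 lists had adjusted p = 0.411 each with an estimated correlation. Adipocyte genes rose in 8 of 11 members (11 adjusted over the list alone, adjusted p = 0.645 with an estimated correlation), with Fabp4 at 260 ± 207 against 15.6 ± 4.97 CPM, and the list scores were 2.76 and 2.46 in berberine replicates 1 and 2 and -1.67 in berberine replicate 3.

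The remaining lists had no call at the preset correlation. Members higher and lower were 2 and 1 of 20 for interferon response, 4 and 1 of 16 for tight and adherens junctions, 3 and 3 of 14 for fatty acid synthesis, 2 and 0 of 20 for cholesterol synthesis, and 0 and 2 of 11 for oxidative stress response. They were 5 and 2 of 14 for unfolded protein and amino acid stress response, 1 and 1 of 19 for glycolysis and hypoxia, and 3 and 2 of 12 for immediate early genes. They were 0 and 1 of 5 for tuft cells, 0 and 3 of 5 for neutrophils, 1 and 1 of 11 for macrophages, 0 and 0 of 12 for smooth muscle, 2 and 2 of 15 for fibroblasts and matrix, 3 and 1 of 9 for endothelium, 0 and 1 of 8 for enteric neurons and glia, 0 and 0 of 1 for pancreatic acinar cells, and 1 and 0 of 8 for posterior Hox genes. Adjusted over the list alone, the counts differed for interferon response (0 and 1), fatty acid synthesis (4 and 3), cholesterol synthesis (0 and 0), oxidative stress response (0 and 1), unfolded protein and amino acid stress response (6 and 2), endothelium (4 and 1) and enteric neurons and glia (0 and 0). Among these, Cldn4 fell by 3.16 ± 0.27, Jun fell by 1.44 ± 0.15 and Pfkp, a glycolytic enzyme, rose by 1.21 ± 0.12 on the log2 scale. Mt2, a metallothionein, was 17.3 ± 7.82 against 109 ± 41.4 CPM. Without high-fat diet replicate 3 the smooth muscle, neuron and glia, and neutrophil lists gained a call (adjusted p = 4.59e-08, 0.000144 and 0.00363). Without high-fat diet replicate 1 the endothelium list did (0.0376), and without berberine replicate 2 or high-fat diet replicate 2 the interferon list did (0.00985 and 0.00799). Median, mean and camera direction differed in sign for fatty acid synthesis, cholesterol synthesis, phospholipid metabolism, fibroblasts and matrix, and the added general epithelium list. General epithelial genes rose in 1 and fell in 2 of 18 members, without a camera call (adjusted p = 0.679).

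Among large changes, Slc30a10 was 66.0 ± 12.5 against 0.214 ± 0.256 CPM, and the metabolic genes Ces1e, Cyp2e1, Selenbp2 and Pck1 rose by 6.07 ± 0.91, 5.79 ± 1.16, 5.30 ± 0.31 and 4.92 ± 0.48 on the log2 scale. Cyp2e1 was at 117 and 73.3 CPM in berberine replicates 1 and 2 and at 2.79 CPM in berberine replicate 3. T, Defa35, Cyp21a1, Upk3a and Cldn6 were at 0 in every berberine library, and so at least 533-fold, 380-fold, 362-fold, 198-fold and 152-fold lower than under high-fat diet. As against chow, the bound of T rests mostly on high-fat diet replicate 1. Without berberine replicate 2, 2960 genes changed, and without berberine replicates 1 and 2 together 1321 did, where the lone berberine library is assumed to vary like the other groups. With scaling by library totals alone the median of all genes was -0.116, against -0.007 with TMM, and edgeR gave 1864 genes higher and 2689 lower, 40.9% higher in place of 51.4%. In 50.4% of genes the groups did not overlap, where chance gives 10%.

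**Figure D2:**
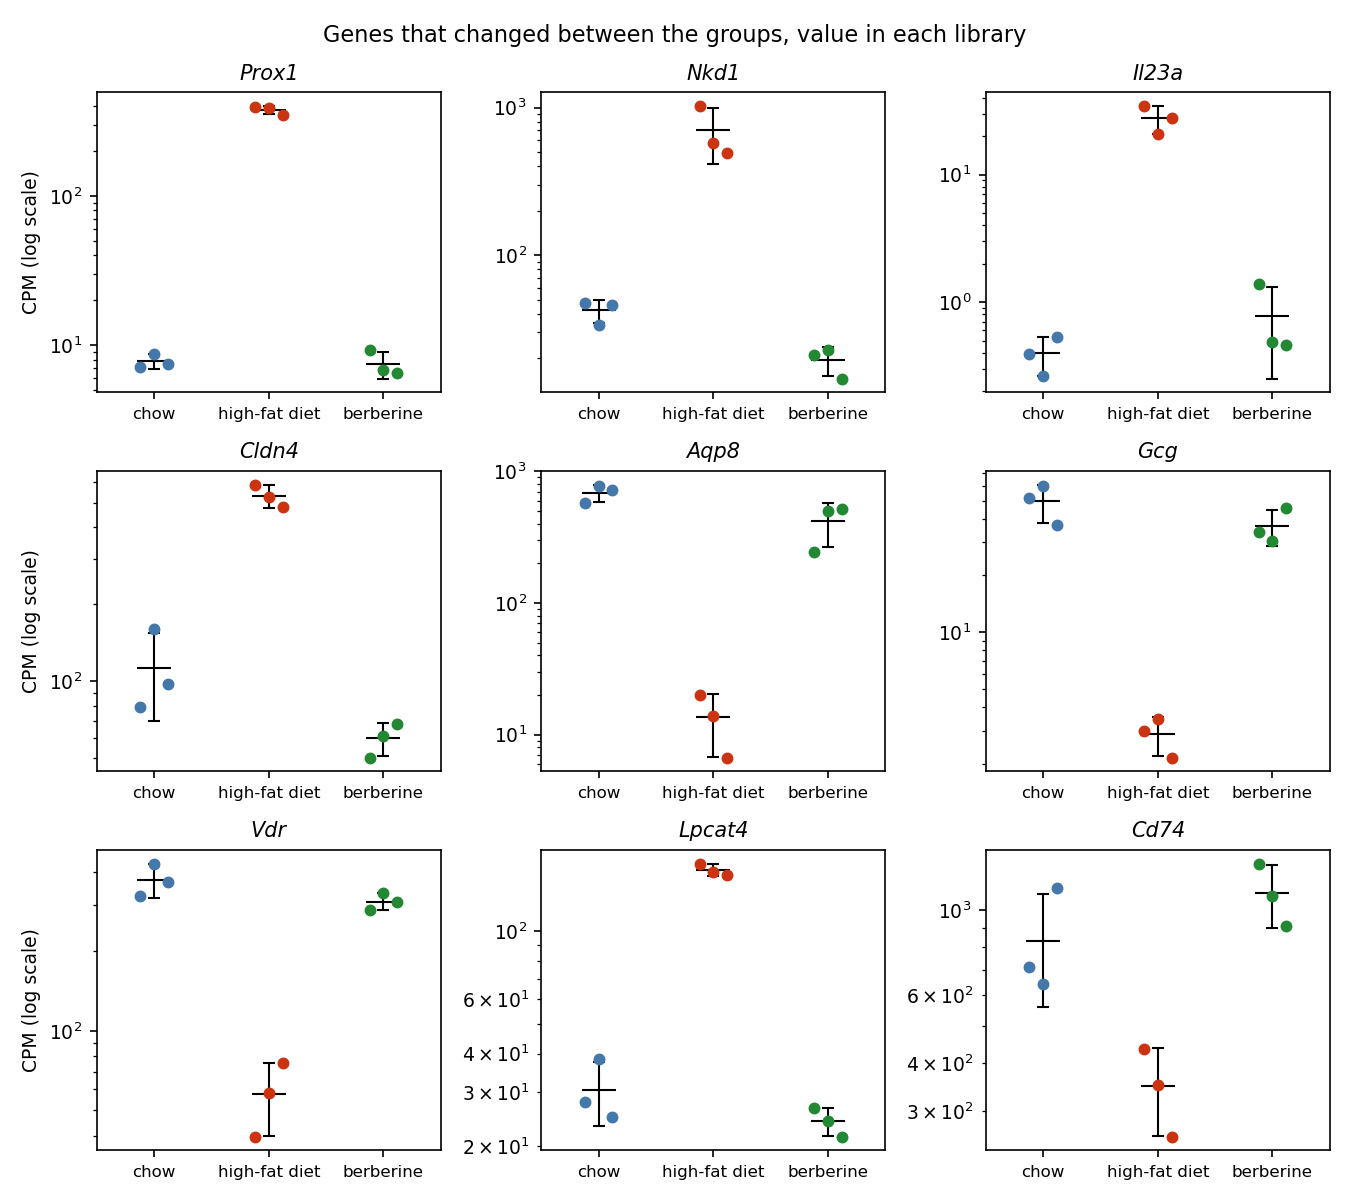
Points are CPM values of single libraries on a log scale for 9 genes, and the bars give the mean ± SD of 3 libraries per group. Prox1 averaged 7.82, 378 and 7.52 CPM in the chow, high-fat diet and berberine libraries, and Aqp8 averaged 689, 13.5 and 420.2 CPM.

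The changes in these comparisons were then set against each other, gene by gene. Of the 2199 genes higher under high-fat diet than under chow, 1649 (74.99%) were lower with berberine than under high-fat diet, where 328.7 would be shared by chance, and of the 2414 lower genes 1752 (72.6%) were higher with berberine, where 381.4 would be. Prox1, Notum, Il23a and Mcpt1 were among the former and Aqp8, Gcg, Vdr and Cd74 among the latter. A total of 3401 genes were called in opposite directions by edgeR and 3 in the same direction. Relative to chow, the genes called higher under high-fat diet had a median log2 fold change of 0.91 under high-fat diet and 0.10 with berberine. The genes called lower had -1.20 and -0.12. These genes were chosen by their difference between the same high-fat diet and chow libraries, which by itself enlarges the high-fat diet medians. Across genes, which are not independent replicates, the fold changes had r = -0.86 and a covariance of -1.59. Both comparisons use the same 3 high-fat diet libraries. Sharing them by itself gave a mean r of -0.50 and a covariance of -0.10 in 20 simulations without any change. These simulations called 0 genes in opposite directions, but with no change hardly any gene can be called at all. That 0 therefore does not measure how far sharing adds to the 3401. The high-fat diet libraries were too few to be divided between the comparisons, so the contribution of sharing them was not removed from these counts. Without berberine replicates 1 and 2 the count was 1214, without chow replicates 1 and 3 it was 2238, and without chow replicates 2 and 3 it was 1830. Each of these fits has 1 library in a group, which is assumed to vary like the libraries of the other groups.

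**Figure D3:**
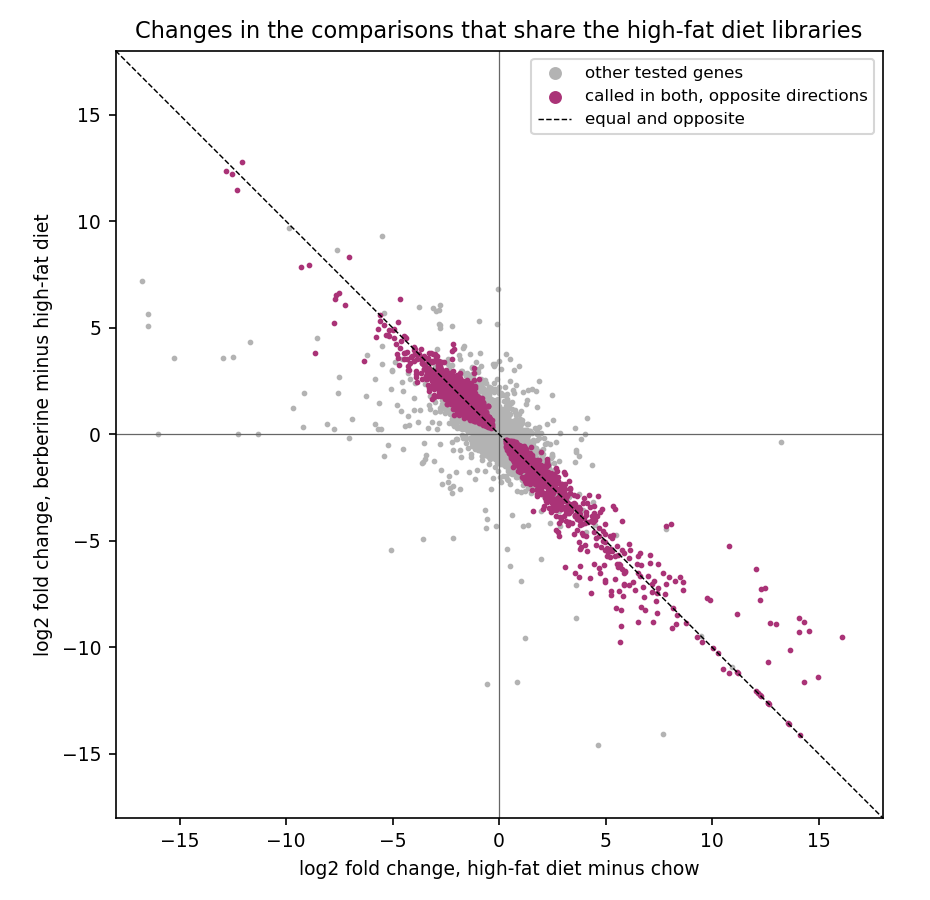
Each point is 1 of 14506 genes, with the log2 fold change of high-fat diet minus chow on the horizontal axis and of berberine minus high-fat diet on the vertical axis, and coloured points are the 3401 genes called in both with opposite signs. The shared high-fat diet libraries pull the points towards the dashed line of equal and opposite change, and values beyond about 10 belong mostly to genes at 0 in a group, whose fitted fold changes are no measure of size.

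Berberine was last compared with chow, which asks how far the berberine libraries differed from chow. Few genes passed the edgeR test between these groups, and 3 of the 7 that did encode chaperones or co-chaperones of the heat shock system, which were higher with berberine. Hsph1, a chaperone of the Hsp110 family, was 157 ± 27.1 against 35.3 ± 8.21 CPM (log2 fold change 2.15 ± 0.25), Dnaja1, an Hsp40 co-chaperone, was 331 ± 24.8 against 148 ± 10.03 CPM (1.16 ± 0.11) and Chordc1, an Hsp90 co-chaperone, was 87.0 ± 8.35 against 44.8 ± 3.34 CPM (0.96 ± 0.12). Gsk3b, a kinase that acts in Wnt and insulin signalling (ENSMUSG00000022812, chromosome 16, 38089001 to 38246084), was 91.0 ± 2.96 against 22.5 ± 2.97 CPM (2.02 ± 0.14), and Cacna1h, a calcium channel gene, was 29.4 ± 2.57 against 56.6 ± 3.43 CPM (-0.95 ± 0.12). By edgeR, 7 genes changed, 6 upward and 1 downward, with adjusted p = 0.00369 for Gsk3b, 0.0155 for Dnaja1 and 0.0487 for Hsph1, Chordc1 and Cacna1h. The others were Gm8355 (2.66 ± 0.33) and Gm15459 (1.41 ± 0.16), predicted genes outside the naming rule that were named after their values were seen. They had 5 and 6 near-identical copies, and Gm15459 matched Hspa8 at 99.8% identity over 916 bases, so these calls were not shown to be separate from those copies. Dnaja1 had 4 near-identical copies, and the other called genes had 0 by BLAST. All 7 genes were also called in high-fat diet against chow. Under high-fat diet Gsk3b averaged 86.9 ± 10.6 and Dnaja1 283 ± 2.24 CPM.

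The calls of these genes depended on single libraries, except that of Gsk3b. Gsk3b kept its call without each single library. Dnaja1 lost its call without berberine replicate 2 (0.145) or 3 (0.0551), high-fat diet replicate 1 (0.0575), or chow replicate 1 (0.0546) or 3 (0.0794). Hsph1 lost it without berberine replicate 1 (0.0894), 2 (0.154) or 3 (0.0873), high-fat diet replicate 1 (0.0634) or 2 (0.0883), or chow replicate 1 (0.191), 2 (0.123) or 3 (0.128). Chordc1 and Cacna1h lost theirs without each of the 9 libraries, with adjusted p from 0.0764 without high-fat diet replicate 3 to 0.224 for Chordc1 without chow replicate 1 and 0.171 for Cacna1h without berberine replicate 1. The number of genes called was 1 without berberine replicate 2, high-fat diet replicate 1 or chow replicate 3, 3 without berberine replicate 3, high-fat diet replicate 2 or chow replicate 1, and 4 without berberine replicate 1 or chow replicate 2. At an unadjusted p under 0.05 there were 1579 genes, where 725 are expected by chance, and DESeq2 called 384. The groups did not overlap in 18.1% of genes, where chance gives 10%.

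**Figure D4:**
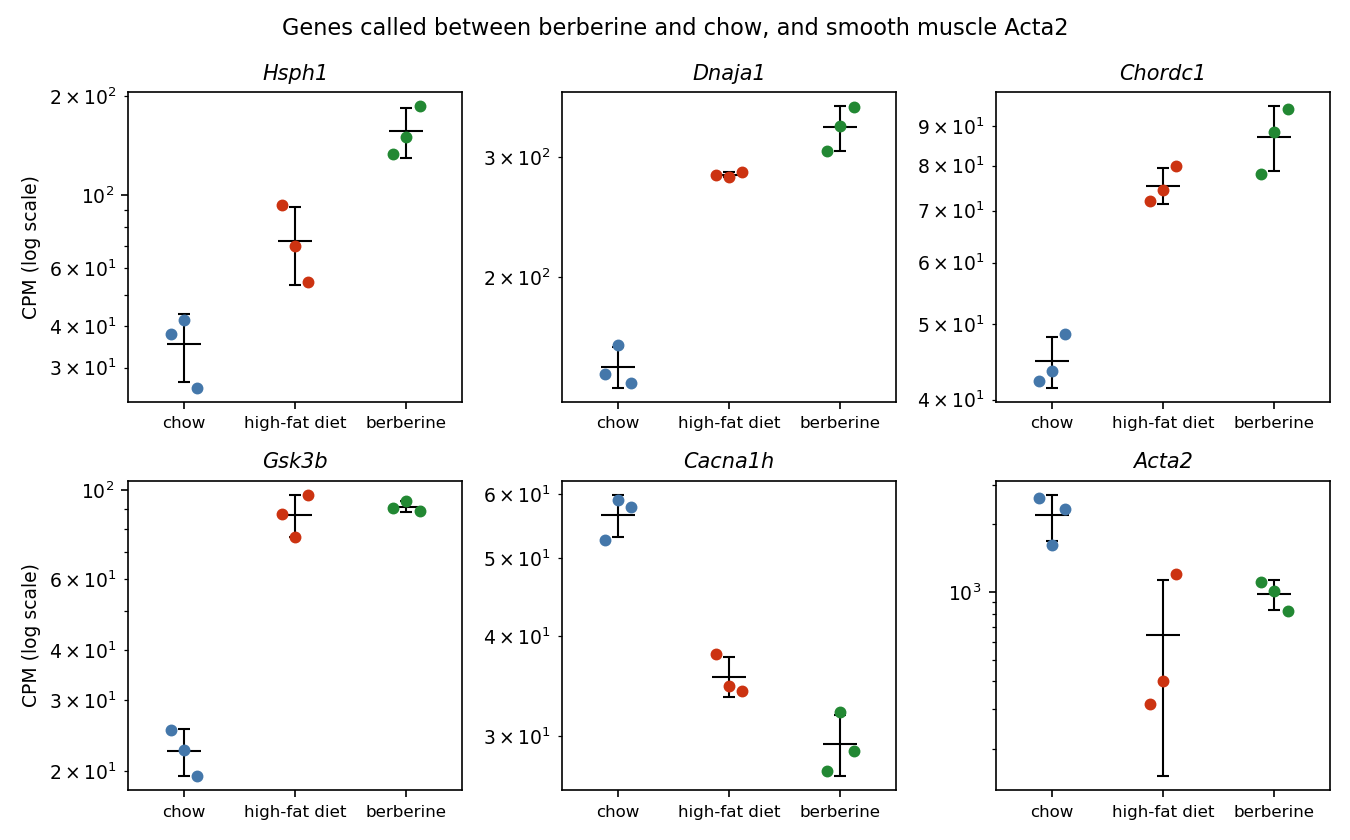
Points are CPM values of single libraries on a log scale for the 5 named genes that differed between berberine and chow and for Acta2 of smooth muscle, with bars for the mean ± SD of 3 libraries per group. Gsk3b averaged 22.5, 86.9 and 91.0 CPM in the chow, high-fat diet and berberine libraries.

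Heat shock proteins, a list written after Hsph1, Dnaja1 and Chordc1 had been seen, rose in 3 of 15 members (14 adjusted over the list alone), with a median of 0.87. Without those 3 genes, 11 of 12 members were higher adjusted over the list alone, with a median of 0.69 and an unadjusted camera p = 0.000874 with an estimated correlation. Hspa1a, the inducible Hsp70, was 132 ± 28.4 against 35.7 ± 11.3 CPM (adjusted p = 0.152 by edgeR). The same list was higher in 8 and lower in 2 of 15 members in high-fat diet against chow (8 and 2 adjusted over the list alone, adjusted p = 0.567 with an estimated correlation), and 4 were higher in berberine against high-fat diet (4 adjusted over the list alone, adjusted p = 0.617).

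Of the 37 fixed lists, 13 were called at the preset correlation, 7 upward and 6 downward, but 0 with an estimated correlation, 0 by fry, and no member gene passed over all genes. Upward were unfolded protein and amino acid stress response (5 of 14 members adjusted over the list alone), follicular B cells (0 of 14), plasma cells (4 of 9), mast cells (0 of 9), macrophages (1 of 11), adipocytes (0 of 11) and MHC class II (0 of 9), with adjusted p = 0.399, 0.552, 0.434, 0.552, 0.552, 0.647 and 0.751 with an estimated correlation. Downward were smooth muscle (0 of 12), xenobiotic response (4 of 14), fatty acid oxidation and PPAR targets (1 of 20), bile acid handling (0 of 11), squamous epithelium (0 of 9), and enteric neurons and glia (1 of 8), with adjusted p = 0.552, 0.399, 0.647, 0.552, 0.552 and 0.647. Creld2, an endoplasmic reticulum chaperone, was 85.2 ± 8.64 against 41.0 ± 2.89 CPM (adjusted p = 0.0793 by edgeR), Derl3 was 10.4 ± 1.37 against 3.95 ± 1.71 CPM (0.314) and Cyp2c55 was 55.1 ± 15.4 against 1527 ± 1655 CPM (0.142). For Cyp2c55, berberine against chow, the log2 fold change was -4.79 with all libraries and -3.40 without chow replicate 2, which held 3419 CPM. Smooth muscle scores lay between -1.34 and -1.03 in the berberine libraries and between -0.30 and 0.20 in chow, with Actg2 at 453 ± 67.7 against 1389 ± 170 CPM (adjusted p = 0.343 by edgeR). Added lists of striated muscle and proximal colon were lower in 10 of 10 and 4 of 6 members adjusted over the list alone, but in 0 over all genes. Camera gave adjusted p = 0.21 and 0.189 with an estimated correlation, and the high values again lay in chow replicates 3 and 2. The estimated correlations between members were 0.833 and 0.798, so the members do not count as separate observations. Among the other 24 fixed lists, adjusted over the list alone 2 glycolysis and hypoxia members, 1 immediate early gene and 1 absorptive colonocyte gene were higher, and 1 absorptive colonocyte gene and the 1 tested pancreatic acinar gene were lower.

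At the preset correlation 6 of the 10 splits of the berberine and chow libraries, the real one among them, gave at least 13 called lists. Calls at that setting, whether kept, lost or gained below, therefore do not by themselves set berberine apart from chow. Several of these list calls also rested on single libraries. For the adipocytes list, berberine against chow, the call was lost without berberine replicate 1 (adjusted p = 0.138) or 2 (0.0722). The scores of those libraries were 2.76 and 2.46, and that of berberine replicate 3 was -1.67. The squamous direction turned without chow replicate 1 (0.989). The MHC class II call was lost without berberine replicate 1 (0.387) or chow replicate 1 (0.202) or 2 (0.402). That of fatty acid oxidation was lost without berberine replicate 1 (0.0531) or 3 (0.121) or chow replicate 2 (0.761), and that of bile acid handling was lost without berberine replicate 1 (0.102) or 2 (0.0673) or chow replicate 2 (0.26) or 3 (0.0605). The neuron and glia call was lost without berberine replicate 1 (0.0929) or 2 (0.136) or any chow replicate (0.0663, 0.0507 and 0.156). Calls appeared without chow replicate 3 for cell division (0.00303), cholesterol synthesis (0.00401), glycolysis and hypoxia (0.0074), T and NK cells (0.0147), immediate early genes (0.0167) and absorptive colonocytes (0.0346). Without chow replicate 2 they appeared for goblet cells (0.00839), antimicrobial proteins (0.014), Wnt targets (0.0221) and posterior Hox genes (0.0229), and without chow replicate 1 for oxidative stress response (0.0202). Without berberine replicate 1 they appeared for Wnt targets (0.0027) and glycolysis (0.0108). They appeared without replicate 2 for tuft cells (0.0134) and inflammatory mediators (0.0301), without replicate 3 for inflammatory mediators (0.00143) and fatty acid synthesis (0.0138). The same held without high-fat diet replicate 1 or 3 for inflammatory mediators (0.0362 and 0.0222) or, without replicate 3, glycolysis (0.047). Median, mean and camera direction differed in sign for interferon response, antimicrobial proteins, tight and adherens junctions, fibroblasts and matrix, and immediate early genes.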

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

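DESeq2, library totals without TMM, counts divided by 4 and the pairs of libraries left out were chosen after seeing the data. Limma on log2(FPKM + 1) was the main test of the written design, and edgeR took its place after the table was seen to hold counts. The other alternatives were planned, but most were run with edgeR. Leaving out a pair leaves 1 library in that group, which is assumed to vary like the libraries of the other groups, so these values rest on that library and do not test how stable a result is. Over the alternatives, genes changed in high-fat diet against chow ranged from 2001 to 5585, in berberine against high-fat diet from 1321 to 5474, and in berberine against chow from 1 to 455. Genes called in opposite directions ranged from 1214 to 4182. The Wnt target list kept its call under all 32 alternatives in both comparisons with high-fat diet.

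Some rules and groups moved the counts beyond 1.5 times. Genes changed were 2462 and 2371 at 2-fold or more in high-fat diet against chow and berberine against high-fat diet, 2794, 2709 and, in berberine against chow, 455 (5 shared with the 7 of the main test) at an unadjusted p under 0.05 with 2-fold, and 3008 and 2855 at 5 FPKM or more, where the reversal count was 2263. Without berberine replicates 1 and 2 the counts were 1321 in berberine against high-fat diet, 3 in berberine against chow (0 shared) and 1214 for the reversal. Without chow replicates 1 and 3 they were 2756 in high-fat diet against chow, 71 in berberine against chow (1 shared) and 2238 for the reversal, and without chow replicates 2 and 3 they were 2001, 1 (0 shared) and 1830. The unadjusted rule drops the correction over all genes, which by itself raises a count. The filter at 5 FPKM tested 8187 genes in place of 14506. The cause of the higher count in berberine against chow without chow replicates 1 and 3 was not tested.

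In berberine against chow 2 genes, both among the 7, were called with a filter at 0.1 FPKM, median-of-ratios scaling, robust quasi-likelihood, annotated symbols only or counts divided by 4. With only the 2 groups compared, or the replicate number as a block, 2 genes were called, of which 1 was among the 7. TPM scaling or no abundance trend called 3, all among the 7, and array weights called 30 and DESeq2 384, each with all 7. The cause was not tested. Leaving out single libraries gave 1 to 7 genes there, 2960 to 4740 in berberine against high-fat diet, 3573 to 4325 in high-fat diet against chow, and 2449 to 3261 for the reversal.

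With an estimated correlation 2, 1 and 0 lists were called in the comparisons in the order of the report, and fry called 16, 16 and 0. At a pseudocount of 0.1, 7 lists were called in berberine against chow. Without single libraries the list counts were 18 to 21, 18 to 22 and 10 to 17. With berberine replicate 3 as the lone berberine library, without replicates 1 and 2, directions reversed for the adipocytes list, berberine against chow (adjusted p = 2.23e-09) and against high-fat diet (0.883). With chow replicate 2 as the lone chow library, without replicates 1 and 3, they reversed for the antimicrobial proteins list, berberine against chow (2.59e-05), and there also for posterior Hox genes (0.00154), regenerative epithelium (0.0377) and squamous epithelium (0.556). The squamous epithelium list, berberine against chow, ran from adjusted p = 5.48e-06 without chow replicate 2 to 0.989, reversed, without chow replicate 1. For Gsk3b, berberine against chow, adjusted p was 0.113 with berberine replicate 3 as the lone berberine library and 0.0699 with chow replicate 1 as the lone chow library. Among named genes 870 results lost their call, 191 gained one and 0 that were called changed sign, while 59 results that were called neither in the main test nor in the alternative changed sign. Among lists 161 results lost their call and 95 gained one, where a result is 1 list or gene in 1 comparison under 1 alternative. Replicate numbers gave no clear pairing of the samples, with 3 of 9 same-number correlations above 0.1. These 9 ran from -0.071 to 0.139 and the different-number ones from -0.193 to 0.169, so pairing was neither shown nor excluded.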

Other observations

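The tests of explanations in this part, among them those on epithelium, position, tumour tissue, copies, smooth muscle, handling and other tissues, were chosen after the results were seen, while the counts over other splits of the libraries were planned.

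The high-fat diet libraries stood apart from the other groups. A lower share of epithelium was argued against, since general epithelial genes had a median log2 fold change of -0.1647 over 25 genes and absorptive colonocyte genes -2.6256. The 10 members not seen before that list was written had a median of -0.0202. Another position along the colon was not decided. The other 6 libraries spanned 9.73 on the first principal component, although their posterior Hox scores ran from -1.264 to 0.862. The gap to the high-fat diet libraries was 137.05. Hox differences among those 6 libraries thus came with little shift along this component. But the component mostly separates the high-fat diet libraries, and the test was chosen after its values were seen. Hox scores under high-fat diet ran from -0.0588 to 0.8663, with 0 of 8 genes higher and 1 lower than in chow. Of the proximal colon genes 4 of 6 fell, with the high values in chow replicate 2. More tumour tissue in the high-fat diet samples may be a source and stayed open, with Wnt target scores of at least 2.8018 there and at most 0.0709 elsewhere, and so did the diet itself, which was not tested apart from it.

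Heat shock genes were higher in the berberine than in the chow libraries. Reads shared with near-identical copies were argued against, since the 8 heat shock genes without such a copy had a median of 0.7734, and 2 of the 3 called heat shock genes, Hsph1 and Chordc1, had none. A lower share of smooth muscle was argued against as the whole cause, since the upper quartile of the medians of the other lists was 0.3146 against 0.8667 for heat shock genes. Handling of the tissue before RNA extraction could also raise these genes and stayed open, since immediate early genes had a median of -0.0094 with 6 higher and 6 lower, from -0.836 to 1.073. An effect of berberine was not tested apart from it.

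Genes of other tissues were high in some libraries, and no biological explanation was tested. Striated muscle in chow replicate 3 may be the source there, with 10 of 10 genes over 4 times as high as in any other library. Fat tissue in berberine replicates 1 and 2 may be the source of the adipocyte genes, with 10 of 11 genes over 4 times as high as in berberine replicate 3. Squamous epithelium in chow replicate 1 stayed open, with 6 of 9 genes over 4 times as high as the median of the other libraries. The squamous score was also raised in the high-fat diet libraries (1.19, 1.51 and 0.74), so this pattern was not confined to chow replicate 1.

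Each comparison allows 10 splits of 6 libraries, too few for a share under 0.05. In high-fat diet against chow the real split gave 4613 genes (1 split as large, highest other 1) and 19 lists (3 splits as large, highest other 24). In berberine against high-fat diet it gave 4460 genes (1 split, highest other 3) and 19 lists (3 splits, highest other 20), and in berberine against chow 7 genes (1 split, highest other 0) and 13 lists (6 splits, highest other 19). For the reversal, 1 of 100 assignments of the 9 libraries, the real one, gave as many as 3401 genes, with 1 as the highest other. No other assignment drawn had the high-fat diet libraries as the group shared by both comparisons. The count therefore shows that the high-fat diet libraries stood apart, and it cannot test a reversal by berberine.

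Terms paired with genes in the table were tested as well. At the preset correlation 148 of 3453 terms were higher and 149 lower in high-fat diet against chow, 126 and 81 in berberine against high-fat diet, and 101 and 40 in berberine against chow, with 0 by camera with an estimated correlation. Ribosome biogenesis rose in 61 of 99 genes and fell in 1 under high-fat diet, and rose in 1 and fell in 46 with berberine against high-fat diet (adjusted p = 0.777 and 0.857 with an estimated correlation). Valine, leucine and isoleucine degradation fell in 25 of 44 genes and rose in 0 by edgeR under high-fat diet, and rose in 21 and fell in 1 with berberine (adjusted p = 0.777 and 0.857 with an estimated correlation). In berberine against chow, immunoglobulin receptor binding had the smallest p, with a median of 1.233 and 0 of 67 genes called (adjusted p = 0.996 with an estimated correlation). Immunoglobulin and T cell receptor segments held 1.01% to 1.31% of counts in the berberine libraries and 0.31% to 0.86% in chow. Of 181 such segments 0 rose and 0 fell there.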
